A study of Danio rerio with 16 samples.

How the data were processed

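RNA was sequenced from livers of zebrafish larvae at 4 to 7 dpf, in 8 groups with 2 libraries each and 30 larvae per library. Per the labels' protocols, RNA was extracted with a ReliaPrep kit, libraries were made with a directional NEBNext Ultra II kit and paired reads of 150 bases came from a NovaSeq. Per the submitters' processing notes, the authors aligned reads to GRCz11 with HISAT2 and counted them per gene with featureCounts; tool versions, the strand setting and the annotation release are not given in the sources used here. The deposited values are raw counts per gene, with EGFP counted as an additional feature. Per the series design text, the authors tested genes in iDEP 0.951 at a false discovery rate of 0.1 and a fold change of 2.

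The values were whole numbers with no sign of filtering or scaling. Between 70.3% and 77.8% of values from 1 to 50 were even, against 50.9% to 56.2% of values over 1000, so read pairs may have been counted per mate; the same tests were therefore repeated with every count halved. Of 32058 features, 32057 carried Ensembl gene identifiers, 28988 of these were found in the gene name table, 6166 had 0 counts in every library, and 531 symbols stood on more than 1 feature. Gene symbols and identifiers are those of the deposited file.

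Groups, comparisons, tests, gene lists and alternatives were chosen before the data were examined, apart from those named below as chosen after. Counts were tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test, robust dispersions, TMM scaling and the default filter on low counts by group. A single model held all 16 libraries with a coefficient per group and 8 residual degrees of freedom, and 17799 genes were tested. Libraries held 23462617 and 23329682 counts at 4 dpf, 22301983 and 23755352 at 5 dpf, 24215932 and 20480078 in 6 dpf fasted wild type, 25046196 and 19836294 in GCaMP, and 28033476 and 22772018 with ethanol. At 7 dpf they held 25366839 and 20679134 when fasted, 18995692 and 22328198 when fed, and 23216544 and 19541826 in ventral. Normalization factors ran from 0.837 to 1.3. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called changed (rose or fell) at an adjusted p under 0.1 with a fold change of at least 2, the limits the series design text gives. The 8 comparisons were ethanol against none at 6 dpf fasted, GCaMP against wild type at 6 dpf fasted, fed against fasted and ventral against fed at 7 dpf, and 5 against 4 dpf, 6 dpf fasted against 5 dpf, 7 against 6 dpf fasted and 7 dpf fasted against 4 dpf. Replicate numbers were not treated as pairs.

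For 41 gene lists of liver pathways and of marker genes for other cell types, drawn from general knowledge, members changed were counted with adjustment over all genes and again adjusted over the list alone. Each list was compared with the other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 41 lists of a comparison, called at an adjusted p under 0.1, and repeated with an estimated correlation. Lists of ribosomal proteins, oxidative phosphorylation and the proteasome were gathered by symbol pattern and caught members that are not subunits. Of these, 11, 13 and 1 were recognized by name, and counts without them are given where they matter. Others may remain. Symbols of tandem duplicates such as globins, elastases and trypsins share sequence, and their counts may be divided unevenly among copies. Genes named in the text were, per comparison, the 6 called genes with a gene symbol and the smallest p in each direction, up to 4 called members per list with the largest fold changes, and the 2 most abundant members of each marker list, called or not; where no member of a list was called, its 2 most abundant could be named. Fewer are printed where a list is given by its counts.

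Levels are CPM, counts divided by the TMM-scaled library size, as mean ± SD of 2 libraries, and differences are log2 fold changes ± standard error. The standard error is the absolute log2 fold change divided by the square root of the F statistic, so it restates that test. A floor of 3 counts corresponds to 0.0827 to 0.165 CPM per library; for genes with 0 counts in a group the fold is a lower bound at 3 counts over that group. These floors cover counting error only. If read pairs were counted per mate, 3 counts are fewer than 3 pairs and the lower bounds are too high. On counts simulated for the ethanol comparison (17033 genes), edgeR recovered 80 of 100 genes changed 3-fold and 94 of 100 changed 6-fold with 10 false calls. DESeq2 1.42.0 recovered 82 and 97 with 19 false calls (17799 genes). A recovered gene had to have the right direction in edgeR, while for DESeq2 the direction was not checked. The simulated changes left out scarce genes, went up and down in equal numbers, and no other gene changed. The real comparison had 4089 changed genes, so these rates do not carry over to it.

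The alternatives were RLE size factors, library size alone, no count filter, a CPM of at least 0.5 in 1 library, an adjusted p under 0.05, no fold limit, DESeq2, limma voom with sample weights, only the libraries of both groups, a replicate block, leaving out each library, ethanol against the mean of wild type and GCaMP, and the estimated correlation. Chosen after seeing the data were marker scores of 3 lists (pancreas, skin and red blood cells) as covariates, and halved counts. Transcript isoforms, splicing and reads themselves were not analysed here.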

Results

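Livers of zebrafish larvae were sequenced in 8 groups of 2 libraries (n = 2), each library holding the livers of 30 larvae. The groups were 4 and 5 dpf (days post fertilization) kept normally, 6 dpf fasted as wild type, as Tg(fabp10a:GCaMP6s) or with ethanol, and 7 dpf fasted, fed and fed ventral. Of 17799 genes tested, the number that changed at least 2-fold (adjusted p under 0.1) ran from 171 (GCaMP against wild type) to 6953 (7 dpf fasted against 4 dpf). The p-values measured only the spread between libraries, since the labels do not say whether pools came from separate clutches. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so levels are given as mean ± SD without a test of their own. Gene differences are log2 fold changes ± SE, list medians are medians of log2 fold changes, and lists were tested by camera with Benjamini-Hochberg adjustment.

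The first principal component held 45.3% of the variance. It separated fed libraries at 7 dpf (-104 and -97.5) and 4 dpf libraries (-85.4 and -84.5) from fasted libraries at 6 dpf (88.7 and 93.3) and 7 dpf (88.6 and 90.5). Libraries at 5 dpf lay between them (-7.21 and -13.4). The second component (13.2%) set the ethanol libraries apart at 100.9 and 109.7. On the first component the ethanol libraries lay at 38.6 and 39.8, between those of 5 dpf and 6 dpf fasted. Replicates correlated at r = 0.957 to 0.976 across genes, which are not independent of each other. The ventral replicates correlated less with each other (0.957) than the closest pair of a ventral and a fed library (0.967).

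Transcripts of endoplasmic reticulum (ER) chaperones, the proteasome and cytosolic heat shock proteins were higher in 6 dpf fasted livers with ethanol than without. Those of alcohol-metabolizing enzymes, bile acid enzymes and the circadian clock were lower, and times of collection are not given in the sources used here. calr3b (ENSDARG00000102808), a calreticulin that helps new glycoproteins fold, stood at 327 ± 21.3 CPM with ethanol against 31.2 ± 0.794 CPM without (n = 2 each), 10.5-fold higher. rbp4 (ENSDARG00000101199), the retinol carrier that hepatocytes secrete, stood at 1213 ± 10.7 CPM with ethanol against 9340 ± 460 CPM without (n = 2 each). per2 (ENSDARG00000034503), a light-responsive clock repressor, fell to 9.22 ± 1.43 CPM with ethanol against 159 ± 0.823 CPM without (n = 2 each). The comparison asks how ethanol alters the liver at the same age and food supply, with a dose and duration that are not given in the sources used here.

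The unfolded protein response moved in a single direction, as 22 of 33 rose and 0 fell (median 1.38, camera adjusted p = 3.04e-27, and adjusted p = 0.00163 with an estimated correlation). The folding enzymes pdia4 (3.4 ± 0.17) and sdf2l1 (3.12 ± 0.18) were among its higher genes. Of proteasome subunits 26 of 41 rose and 0 fell (median 1.14, camera adjusted p = 9.35e-21, and adjusted p = 0.0683 with an estimated correlation). Both psmd8 (1.89 ± 0.14) and psmc4 (1.74 ± 0.10) belong to the regulatory cap. Of cytosolic heat shock genes 12 of 28 rose and 2 fell (median 1.31, camera adjusted p = 0.000149, and adjusted p = 0.0965 with an estimated correlation). The stress-inducible chaperone hsp90aa1.2 stood at 180 ± 9.98 CPM with ethanol against 3.71 ± 2.85 CPM without (n = 2 each). Of cholesterol genes 19 of 28 rose and 1 fell (median 2.42, camera adjusted p = 6.58e-07, and adjusted p = 0.472 with an estimated correlation), including the sterol enzymes cyp51 (3.81 ± 0.49) and sqlea (4.39 ± 0.72). The oxidative stress list was mixed, as 10 of 31 rose and 6 fell (median 0.29, camera adjusted p = 0.0271, and adjusted p = 0.584 with an estimated correlation). Both pgd of the pentose phosphate pathway (2.71 ± 0.14) and the peroxide reductase prdx1 (3.04 ± 0.16) rose. That list no longer passed without 6 dpf fasted replicate 2 (camera adjusted p = 0.13) or with marker scores in the model (camera adjusted p = 0.376), that is, with scores for pancreas, skin and red blood cells as covariates, an alternative chosen after seeing the data. The numbers that rose and fell were the same adjusted over the list alone except for heat shock (14 and 2).

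Of alcohol and aldehyde enzymes 1 of 24 rose and 11 fell (median -0.95, camera adjusted p = 5.1e-10, and adjusted p = 0.0683 with an estimated correlation). The alcohol dehydrogenases adh8b (-2.84 ± 0.16) and adh5 (-2.23 ± 0.14) were among those that fell. Of bile acid genes 0 of 21 rose and 10 fell (median -0.67, camera adjusted p = 0.000278, and adjusted p = 0.0644 with an estimated correlation). Of xenobiotic genes 4 of 31 rose and 11 fell (median -0.65, camera adjusted p = 3.27e-05, and adjusted p = 0.0683 with an estimated correlation), with the glutathione transferase gstt1a at -2.23 ± 0.15. Genes of secreted plasma proteins leaned lower, as 5 of 46 rose and 22 fell (median -1.03, camera adjusted p = 2.38e-11, and adjusted p = 0.438 with an estimated correlation). The lipoprotein apoba (-2.5 ± 0.18) and complement c3a.2 (-2.78 ± 0.22) fell. The clock list was mostly lower, as 5 of 37 rose and 20 fell (median -1.46, camera adjusted p = 3.57e-17, and adjusted p = 0.0472 with an estimated correlation). The repressor nfil3-5 (-4.67 ± 0.46) and the nuclear receptor rorcb (-4.85 ± 0.54) were among them. Of ribosomal protein genes 2 of 91 rose and 19 fell (median -0.88, camera adjusted p = 8.48e-13, and adjusted p = 0.584 with an estimated correlation). Without 11 members that are not ribosomal subunits, 0 rose and 19 fell of 80. When adjusted over the list alone, the numbers that rose and fell differed for the clock (5 and 21).

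Outside these lists the liver transcription factor cebpa (2.29 ± 0.18) and the cell cycle inhibitor cdkn1a (2.79 ± 0.19) rose. The DNA repair gene ddb2 (-2.51 ± 0.15) fell. Fatty acid oxidation went both ways, as 2 of 38 rose and 3 fell (median -0.38, camera adjusted p = 0.0839, and adjusted p = 0.775 with an estimated correlation). On this list cpt2 (1.8 ± 0.21) and hadhab (1.5 ± 0.12) were higher and acadm lower (-1.65 ± 0.14). Against the mean of wild type and GCaMP, cpt2 of this list stood at 0.997 and lost its call. That list no longer passed without 6 dpf fasted replicate 1 (camera adjusted p = 0.239) or ethanol replicate 2 (camera adjusted p = 0.302), and its median was 0.08 with scaling by library size alone. Of pancreas markers 2 of 32 rose and 25 fell (median -2.68, camera adjusted p = 0.000278, and adjusted p = 0.693 with an estimated correlation). Of skin markers 1 of 28 rose and 21 fell (median -2.86, camera adjusted p = 1.86e-05, and adjusted p = 0.584 with an estimated correlation). Skin markers took 0.52 ± 0.0986% of counts at 6 dpf fasted and 0.135 ± 0.00302% with ethanol. They took 0.382 ± 0.0205% in GCaMP, 0.0841 ± 0.0305% at 5 dpf and 0.158 ± 0.00216% at 7 dpf fasted. The GCaMP comparison and those of 6 dpf fasted with 5 dpf and with 7 dpf fasted share these 6 dpf libraries. Adjusted over the list alone, the numbers that rose and fell were the same except for pancreas (2 and 26) and skin (1 and 23). In all, 4089 genes changed, 2108 higher and 1981 lower (51.6% higher), by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Libraries of both groups did not overlap for 70% of all genes tested, where chance gives 33.3%. By smallest p the higher genes were xpo1a of nuclear export, calr3b, the amino acid carrier slc38a3a, pgd, gfer and pdia4 (6.54-fold to 18.2-fold). The lower ones were the nucleotide kinase nme4, per2, rbp4, the lipoprotein apobb.2, cyp2u1 and ido1, which degrades tryptophan (6.1-fold to 25.5-fold lower). The highest adjusted p of these 12 was 9.68e-11 (edgeR, Benjamini-Hochberg). Scaling by library size alone moved the median of all genes from 0 to 0.453 and left 80% of changed genes higher (4162 against 1041). A model with marker scores gave 2521 changed genes. Of these 1883 were among the original 4089 with the same sign, and 2206 of the original calls ended.

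Feeding raised transcripts of cell division, fatty acid oxidation, ER folding and the proteasome in 7 dpf livers and lowered endothelial transcripts. cpt2 (ENSDARG00000038618), which delivers acyl groups to mitochondrial oxidation, stood at 133 ± 5.96 CPM when fed against 1.4 ± 0.481 CPM when fasted (n = 2 each). cyp51 (ENSDARG00000042641), a sterol demethylase, stood at 1778 ± 31.3 CPM when fed against 10.2 ± 1.17 CPM when fasted (n = 2 each). The fatty acid elongase elovl2 stood at 1643 ± 182 CPM when fed against 10.1 ± 0.434 CPM when fasted (n = 2 each). The bile acid enzyme cyp7a1 was lower, at 11.9 ± 2.2 CPM when fed against 620.4 ± 92.2 CPM when fasted (n = 2 each). The comparison asks what food changes in the liver at a fixed age.

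Cell division genes moved together, as 49 of 50 rose and 1 fell (median 4.63, camera adjusted p = 1.3e-42, and adjusted p = 0.00528 with an estimated correlation). Of fatty acid oxidation genes 31 of 38 rose and 1 fell (median 2.4, camera adjusted p = 3.4e-31, and adjusted p = 0.0194 with an estimated correlation). The beta-oxidation enzymes decr1 (5.56 ± 0.18), hadh (4.45 ± 0.13) and hadhab (4.23 ± 0.13) rose. Of cholesterol genes 21 of 28 rose and 1 fell (median 5.32, camera adjusted p = 1.73e-15, and adjusted p = 0.128 with an estimated correlation), including sqlea at 7.75 ± 0.73. Genes of fatty acid synthesis went both ways, as 13 of 31 rose and 8 fell (median 0.20, camera adjusted p = 0.00156, and adjusted p = 0.1 with an estimated correlation). The desaturase fads2 (5.26 ± 0.29) and malic enzyme me1 (5.93 ± 0.21) rose. Of ER folding genes 20 of 33 rose and 1 fell (median 1.56, camera adjusted p = 3.71e-16, and adjusted p = 0.00898 with an estimated correlation), with calr3b (4.53 ± 0.16) and pdia6 (3.93 ± 0.17). Of genes on the proteasome list 38 of 41 rose and 0 fell (median 1.81, camera adjusted p = 2.85e-21, and adjusted p = 0.0837 with an estimated correlation), with psmd5 at 2.96 ± 0.22. Of nuclear oxidative phosphorylation genes 64 of 97 rose and 1 fell (median 1.42, camera adjusted p = 2.73e-18, and adjusted p = 0.337 with an estimated correlation). Without 13 members outside the complexes 61 rose and 1 fell of 84. The ATP synthase subunit atp5mc1 stood at 4.24 ± 0.19. The mitochondrial genome moved the other way, as 0 of 13 rose and 9 fell (median -1.38, camera adjusted p = 6.53e-06, and adjusted p = 0.368 with an estimated correlation). Its oxidase subunit mt-co2 stood at -2.11 ± 0.13. The numbers that rose and fell were the same adjusted over the list alone except for oxidative phosphorylation (64 and 2).

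The plasma heme scavenger hpxa (7.76 ± 0.34), the lipid regulator creb3l3a (4.79 ± 0.21) and the glucokinase regulator gckr (6.43 ± 0.67) rose. So did the antioxidant genes gstp1 (5.08 ± 0.15) and prdx1 (4.78 ± 0.17). Of alcohol and aldehyde enzymes 14 of 24 rose and 0 fell (median 1.36, camera adjusted p = 5.23e-06, and adjusted p = 0.128 with an estimated correlation). Of insulin and growth factor genes 3 of 36 rose and 19 fell (median -1.15, camera adjusted p = 0.000387, and adjusted p = 0.271 with an estimated correlation). The nucleolar helicase ddx21 fell (-3.5 ± 0.16). Of endothelial markers 0 of 25 rose and 20 fell (median -1.62, camera adjusted p = 1.63e-10, and adjusted p = 0.0695 with an estimated correlation). The receptor kdrl (-2.25 ± 0.16) and the cadherin cdh5 (-1.85 ± 0.16) fell, and with scores for pancreas, skin and red blood cells in the model they no longer passed (-0.86 and -1.05). Of red blood cell markers 20 of 23 rose and 0 fell (median 4.71, camera adjusted p = 1.34e-06, and adjusted p = 0.235 with an estimated correlation), with the globin hbae3 at 5.42 ± 0.69. Of skin markers 2 of 28 rose and 13 fell (median -2.38, camera adjusted p = 0.0197, and adjusted p = 0.642 with an estimated correlation). Of biliary markers 0 of 16 rose and 2 fell (median -0.69, camera adjusted p = 0.0197, and adjusted p = 0.128 with an estimated correlation). Of intestine markers 10 of 37 rose and 3 fell (median 0.62, camera adjusted p = 0.0396, and adjusted p = 0.516 with an estimated correlation), and this list no longer passed without 7 dpf fed replicate 2 (median -0.19, camera adjusted p = 0.171) or with marker scores in the model (median 1.62, camera adjusted p = 0.104). Intestine markers took 0.515 ± 0.0694% of counts when fed and 0.178 ± 0.0022% when fasted. Of exocrine pancreas markers 2 of 32 rose and 12 fell (median -1.73, camera adjusted p = 0.0396, and adjusted p = 0.728 with an estimated correlation), and this list no longer passed without 7 dpf fasted replicate 2 (median -1.14, camera adjusted p = 0.123). The amylase amy2a fell (-3.08 ± 0.76). When adjusted over the list alone, the numbers that rose and fell differed for the insulin response (3 and 21), endothelium (1 and 20), skin (2 and 14) and pancreas (2 and 8).

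Feeding changed 6673 genes, 3685 higher and 2988 lower (55.2% higher, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Libraries of fed and fasted livers did not overlap for 74.8% of all genes tested, where chance gives 33.3%. The genes higher with the smallest p were gstp1, hadh, ndrg2, cyp2x9, the ubiquitin ligase herc1 and hadhab (14.3-fold to 139-fold). Those lower were cyp2u1, gtpbp4 of ribosome assembly, caprin1b, nop53, the lysosomal carrier slc17a5 and nme4 (6.42-fold to 20-fold lower). Adjusted p of these 12 was at most 1.77e-12 (edgeR, Benjamini-Hochberg). Under a model with marker scores, 1125 genes changed, 72% of them higher. Of 5652 calls that ended there, 4026 missed the limit on adjusted p alone, and the median log2 fold change of all 5652 in the original direction went from 1.8 to 1.46.

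**Figure D1:**
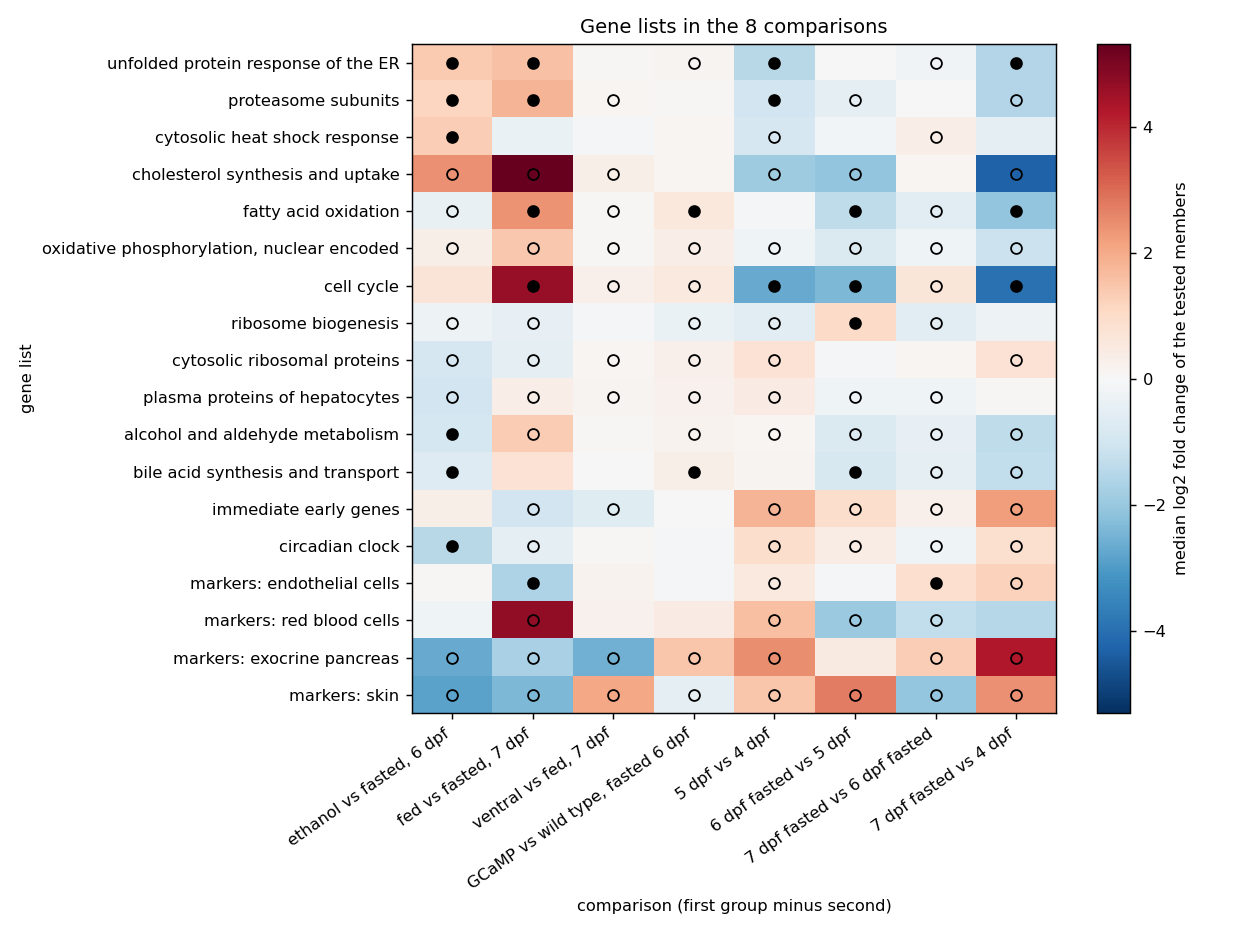
Median log2 fold change of each gene list (down) in each of the 8 comparisons (across), with a filled dot where the list passed in camera also with an estimated correlation and an open dot where it passed with the preset correlation only. The cell cycle list was highest in fed against fasted livers (4.63) and lowest in 7 dpf fasted against 4 dpf livers (-3.95).

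From 4 to 5 dpf, livers lowered transcripts of cell division, ER folding and the proteasome and raised those of several plasma proteins. mki67 (ENSDARG00000091150), a marker of dividing cells, stood at 7.79 ± 0.678 CPM at 5 dpf against 102 ± 11.5 CPM at 4 dpf (n = 2 each). The ER chaperone hsp90b1 stood at 234 ± 17.3 CPM at 5 dpf against 1933 ± 118 CPM at 4 dpf (n = 2 each). ahsg1 (ENSDARG00000026764), which encodes the plasma glycoprotein fetuin, rose to 1113 ± 55.7 CPM at 5 dpf against 122 ± 21.5 CPM at 4 dpf (n = 2 each). The comparison asks how the normally kept liver matures over a day.

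Cell division genes fell together, as 0 of 50 rose and 49 fell (median -2.69, camera adjusted p = 9.79e-53, and adjusted p = 0.00155 with an estimated correlation), with the mitotic kinesin kif20a at -3.75 ± 0.49. In the unfolded protein response 0 of 33 rose and 20 fell (median -1.47, camera adjusted p = 5.1e-41, and adjusted p = 0.000317 with an estimated correlation). The chaperone genes creld2 (-3.45 ± 0.25), hyou1 (-2.94 ± 0.17), calr3b (-2.69 ± 0.15) and dnajb11 (-2.62 ± 0.12) fell. Of proteasome subunits 0 of 41 rose and 21 fell (median -1.01, camera adjusted p = 3.14e-24, and adjusted p = 0.0868 with an estimated correlation), with psmd11b (-1.93 ± 0.14) and psmd12 (-1.67 ± 0.13). Without psmc3ip, which is no subunit, 0 rose and 20 fell of 40. Of cholesterol genes 1 of 28 rose and 19 fell (median -1.89, camera adjusted p = 9.42e-14, and adjusted p = 0.16 with an estimated correlation), with fdps of the isoprenoid branch at -3.35 ± 0.39. Of plasma protein genes 9 of 46 rose and 0 fell (median 0.44, camera adjusted p = 4.38e-12, and adjusted p = 0.245 with an estimated correlation). The fetuin ahsg2 (2.48 ± 0.13), alcohol dehydrogenase adh8a (3.88 ± 0.19), pyruvate kinase pklr (1.86 ± 0.22) and sterol hydroxylase cyp27a7 (1.59 ± 0.13) rose. The numbers were the same adjusted over the list alone.

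Of immediate early genes 13 of 30 rose and 0 fell (median 1.8, camera adjusted p = 1.56e-06, and adjusted p = 0.245 with an estimated correlation). Of clock genes 16 of 37 rose and 3 fell (median 0.93, camera adjusted p = 2.07e-05, and adjusted p = 0.221 with an estimated correlation). Times of collection are not given for these groups either. Of biliary markers 2 of 16 rose and 1 fell (median 0.51, camera adjusted p = 0.00376, and adjusted p = 0.0969 with an estimated correlation). Of exocrine pancreas markers 17 of 32 rose and 0 fell (median 2.46, camera adjusted p = 5.48e-05, and adjusted p = 0.514 with an estimated correlation). Of red blood cell markers 11 of 23 rose and 0 fell (median 1.6, camera adjusted p = 5.12e-06, and adjusted p = 0.245 with an estimated correlation), with the heme enzyme alas2 at 2.42 ± 0.32. The share of counts they took together did not rise, at 0.0747 ± 0.000785% at 5 dpf against 0.0854 ± 0.0161% at 4 dpf. Of skin markers 7 of 28 rose and 0 fell (median 1.49, camera adjusted p = 0.00405, and adjusted p = 0.549 with an estimated correlation). Adjusted over the list alone, the numbers that rose and fell were the same except for immediate early genes (15 and 0), the clock (17 and 3), pancreas (25 and 0) and red blood cells (12 and 0). In all, 2645 genes changed, 1324 higher and 1321 lower (50.1% higher, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and 65.2% of all genes tested did not overlap where chance gives 33.3%. Ranked by p, the higher genes began with ahsg1, upp2, which degrades uridine, adh8a, cbln8, ahsg2 and ido1 (5.57-fold to 14.7-fold). On the lower side came dnajb11, hsp90b1, calr3b, the chromatin protein hmga1a, hyou1 and lamin lmnb1 (4.77-fold to 8.26-fold lower). Among these 12 the highest adjusted p was 1.77e-09 (edgeR, Benjamini-Hochberg). Scaling by library size alone moved the median of all genes from 0.06 to -0.342 and left 17.9% of changed genes higher (597 against 2746). In a model that included marker scores 1070 genes changed.

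From 5 dpf to 6 dpf fasted, livers lowered fatty acid oxidation, cell division and bile acid transcripts and raised ribosome biogenesis. decr1 (ENSDARG00000003869), an auxiliary enzyme for unsaturated fatty acids, stood at 11.6 ± 1.68 CPM at 6 dpf fasted against 125 ± 8.08 CPM at 5 dpf (n = 2 each). The acyl transferase cpt2 stood at 3.77 ± 0.124 CPM at 6 dpf fasted against 73.1 ± 1.65 CPM at 5 dpf (n = 2 each). ppan (ENSDARG00000022232), which matures the large ribosomal subunit, rose to 61.6 ± 4.29 CPM at 6 dpf fasted against 13.3 ± 1.41 CPM at 5 dpf (n = 2 each). Age and the treatment label (Normal to Fast) changed together, so the comparison asks about both at once.

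Fatty acid oxidation fell broadly, as 2 of 38 rose and 24 fell (median -1.35, camera adjusted p = 3.3e-36, and adjusted p = 0.0245 with an estimated correlation), with hadhab (-2.71 ± 0.13) and hadh (-2.6 ± 0.12). Of cell cycle genes 0 of 50 rose and 38 fell (median -2.37, -2.17 with absent members at their bound, camera adjusted p = 5.98e-19, and adjusted p = 0.0245 with an estimated correlation). Of bile acid genes 0 of 21 rose and 7 fell (median -0.86, camera adjusted p = 1.63e-05, and adjusted p = 0.0245 with an estimated correlation). The bile acid receptor nr1h4 (-1.73 ± 0.16) and the racemase amacr (-1.71 ± 0.14) fell. Of ribosome biogenesis genes 28 of 55 rose and 0 fell (median 1.0, camera adjusted p = 8.67e-26, and adjusted p = 0.0756 with an estimated correlation), with nop2 (1.83 ± 0.18) and rrs1 (1.81 ± 0.16). Of biliary markers 2 of 16 rose and 0 fell (median 0.72, camera adjusted p = 0.00242, and adjusted p = 0.0708 with an estimated correlation), with the keratin krt18b at 1.9 ± 0.24. Of cholesterol genes 1 of 28 rose and 18 fell (median -2.09, camera adjusted p = 5.26e-09, and adjusted p = 0.378 with an estimated correlation), with sqlea (-5.46 ± 0.73), cyp51 (-4.9 ± 0.52) and hmgcra (-4.25 ± 0.41). Of nuclear oxidative phosphorylation genes 0 of 97 rose and 28 fell (median -0.78, camera adjusted p = 5.75e-16, and adjusted p = 0.512 with an estimated correlation), with atp5mc1 at -2.52 ± 0.18. Without members outside the complexes 0 rose and 27 fell of 84. The regulators cebpa (-2.14 ± 0.18) and creb3l3a (-3.7 ± 0.19) fell, while foxo1a, a factor that insulin restrains, rose (2.4 ± 0.20). The numbers that rose and fell were the same adjusted over the list alone except for the cell cycle (0 and 40), bile acid genes (0 and 8) and cholesterol synthesis (2 and 18).

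Of skin markers 17 of 28 rose and 0 fell (median 2.73, camera adjusted p = 1.3e-06, and adjusted p = 0.512 with an estimated correlation). Of red blood cell markers 0 of 23 rose and 15 fell (median -1.97, -1.94 with absent members at their bound, camera adjusted p = 4.3e-05, and adjusted p = 0.446 with an estimated correlation). When adjusted over the list alone, the numbers that rose and fell differed for skin (20 and 0). In all, 3238 genes changed, 1420 higher and 1818 lower (43.9% higher, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and 66.2% of all genes tested did not overlap where chance gives 33.3%. By smallest p the higher genes were cyp2u1, the growth factor target etv5b, btg1, the glutamine carrier slc1a5, phf20l1 and isg20 (3.23-fold to 5.9-fold). The lower ones were hsdl2, hadhab, decr1, apobb.2, hadh and cyp2x9 (6.05-fold to 13-fold lower). The highest adjusted p of these 12 was 1.07e-08 (edgeR, Benjamini-Hochberg). With marker scores in the model 1452 genes changed.

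From 6 to 7 dpf under fasting, endothelial transcripts rose as a group. tie1 (ENSDARG00000004105), an endothelial receptor, stood at 145 ± 15.5 CPM at 7 dpf against 60.9 ± 6.64 CPM at 6 dpf (n = 2 each). The growth factor receptor flt1 stood at 62.2 ± 4.96 CPM at 7 dpf against 27.5 ± 4.86 CPM at 6 dpf (n = 2 each). slc38a2 (ENSDARG00000045886), an amino acid carrier, rose to 98.7 ± 25.2 CPM at 7 dpf against 18.3 ± 3.3 CPM at 6 dpf (n = 2 each). The detoxifying transferase gstp1 fell to 23.5 ± 2.08 CPM at 7 dpf against 75.1 ± 3.58 CPM at 6 dpf (n = 2 each). The comparison asks what a further day of age without food changes.

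Endothelial markers moved upward, as 8 of 25 rose and 0 fell (median 0.90, camera adjusted p = 2.35e-15, and adjusted p = 0.0768 with an estimated correlation). Of oxidation genes 0 of 38 rose and 8 fell (median -0.62, camera adjusted p = 2.35e-15, and adjusted p = 0.215 with an estimated correlation), with decr1 (-2.1 ± 0.18), hadh (-1.49 ± 0.13) and acaa1 (-1.31 ± 0.13). Of cell cycle genes 5 of 50 rose and 0 fell (median 0.64, 0.52 with absent members at their bound, camera adjusted p = 5.17e-06, and adjusted p = 0.31 with an estimated correlation). Of ribosome biogenesis genes 0 of 55 rose and 4 fell (median -0.62, camera adjusted p = 6.06e-18, and adjusted p = 0.215 with an estimated correlation). The mitochondrial carboxykinase pck2 (-1.16 ± 0.11) and the clock repressor bhlhe41 (-1.78 ± 0.22) fell. Here too the times of collection are not given. Of skin markers 0 of 28 rose and 12 fell (median -2.04, camera adjusted p = 1.11e-06, and adjusted p = 0.392 with an estimated correlation). Of red blood cell markers 0 of 23 rose and 5 fell (median -1.31, camera adjusted p = 4.31e-05, and adjusted p = 0.392 with an estimated correlation). Of exocrine pancreas markers 5 of 32 rose and 0 fell (median 1.33, camera adjusted p = 2.75e-05, and adjusted p = 0.584 with an estimated correlation). Adjusted over the list alone, the numbers that rose and fell were the same except for the cell cycle (6 and 0), skin (0 and 18) and red blood cells (0 and 9). Changed genes numbered 1212, 478 higher and 734 lower (39.4% higher, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and 54.2% of all genes tested did not overlap where chance gives 33.3%. The genes higher with the smallest p were slc38a2, the photolyase-like cry3a, chn1, dlc1, srgn and zfhx4 (2.25-fold to 5.4-fold). Those lower were ndrg2, aplp1, acad11, which oxidizes long acyl groups, gstp1, spam1 and gcshb of glycine cleavage (3.09-fold to 5.72-fold lower). Adjusted p of these 12 was at most 5.97e-06 (edgeR, Benjamini-Hochberg). Under a model with marker scores 547 genes changed.

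Over the span from 4 dpf to 7 dpf fasted, transcripts of cell division, fatty acid oxidation and ER folding fell and biliary markers rose. hadh (ENSDARG00000030765), a dehydrogenase of beta-oxidation, stood at 8.21 ± 0.143 CPM at 7 dpf fasted against 194 ± 7.27 CPM at 4 dpf (n = 2 each). The ER chaperone calr stood at 22.3 ± 2.13 CPM at 7 dpf fasted against 388 ± 1.88 CPM at 4 dpf (n = 2 each). igfbp1b (ENSDARG00000038666), which binds insulin-like growth factors, rose to 3390 ± 848 CPM at 7 dpf fasted against 12.5 ± 6.13 CPM at 4 dpf (n = 2 each). ucp1 (ENSDARG00000023151), a mitochondrial uncoupling carrier, rose to 23430 ± 1160 CPM at 7 dpf fasted against 1767 ± 326 CPM at 4 dpf (n = 2 each). Age and the treatment label changed together here too.

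Cell division genes fell almost without exception, as 0 of 50 rose and 49 fell (median -3.95, camera adjusted p = 1.77e-31, and adjusted p = 0.0102 with an estimated correlation). Of oxidation genes 1 of 38 rose and 29 fell (median -2.09, camera adjusted p = 2.2e-28, and adjusted p = 0.0257 with an estimated correlation), with decr1 (-5.59 ± 0.18) and cpt2 (-6.85 ± 0.25). In the unfolded protein response 2 of 33 rose and 21 fell (median -1.55, camera adjusted p = 6.48e-21, and adjusted p = 0.0058 with an estimated correlation), with calr3b at -4.75 ± 0.17. Of biliary markers 8 of 16 rose and 0 fell (median 1.01, camera adjusted p = 0.00261, and adjusted p = 0.0755 with an estimated correlation). The keratin krt8 (1.84 ± 0.11) and the annexin anxa4 (2.15 ± 0.13) rose. Of cholesterol genes 2 of 28 rose and 21 fell (median -4.31, camera adjusted p = 5.48e-12, and adjusted p = 0.25 with an estimated correlation), with hmgcs1 (-7.27 ± 0.58) and mvda (-7.01 ± 0.40). Of nuclear oxidative phosphorylation genes 3 of 97 rose and 58 fell (median -1.16, camera adjusted p = 1.14e-14, and adjusted p = 0.419 with an estimated correlation), with atp5mc1 at -4.09 ± 0.19. Without members outside the complexes 3 rose and 54 fell of 84. Of immediate early genes 22 of 30 rose and 0 fell (median 2.23, camera adjusted p = 2.97e-07, and adjusted p = 0.257 with an estimated correlation), with atf3 (5.41 ± 0.53) and btg2 (4.52 ± 0.48). Of ribosomal protein genes 24 of 91 rose and 0 fell (median 0.79, camera adjusted p = 2.63e-07, and adjusted p = 0.622 with an estimated correlation), with rplp2 at 1.89 ± 0.16. Without members that are not subunits, 23 rose and 0 fell of 80. Of endothelial markers 18 of 25 rose and 1 fell (median 1.22, camera adjusted p = 5.22e-07, and adjusted p = 0.118 with an estimated correlation), with kdr (2.01 ± 0.17) and flt1 (2.2 ± 0.15). The mitochondrial oxidase subunit mt-co3 rose (1.93 ± 0.13). Counts adjusted over the list alone did not differ.

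Of exocrine pancreas markers 29 of 32 rose and 0 fell (median 4.27, camera adjusted p = 4.39e-05, and adjusted p = 0.618 with an estimated correlation), with the peptidase cpa1 at 9.36 ± 1.55. Of skin markers 16 of 28 rose and 1 fell (median 2.44, camera adjusted p = 0.00937, and adjusted p = 0.645 with an estimated correlation). The numbers that rose and fell were the same adjusted over the list alone except for skin (18 and 1). This comparison had 6953 changed genes, 3337 higher and 3616 lower (48% higher, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and 76.8% of all genes tested did not overlap where chance gives 33.3%. Ranked by p, the higher genes began with cyp2u1, the nuclear receptor nr5a5, ucp1, upp2, the growth factor receptor fgfr4 and caprin1b (6.44-fold to 17.3-fold). On the lower side came hadh, hadhab, hsdl2, ndrg2, decr1 and hadhb (12-fold to 48.2-fold lower). Among these 12 the highest adjusted p was 1.08e-12 (edgeR, Benjamini-Hochberg). Scaling by library size alone moved the median of all genes from 0.01 to -0.327 and left 32% of changed genes higher (2287 against 4857). In a model that included marker scores 4133 genes changed.

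**Figure D2:**
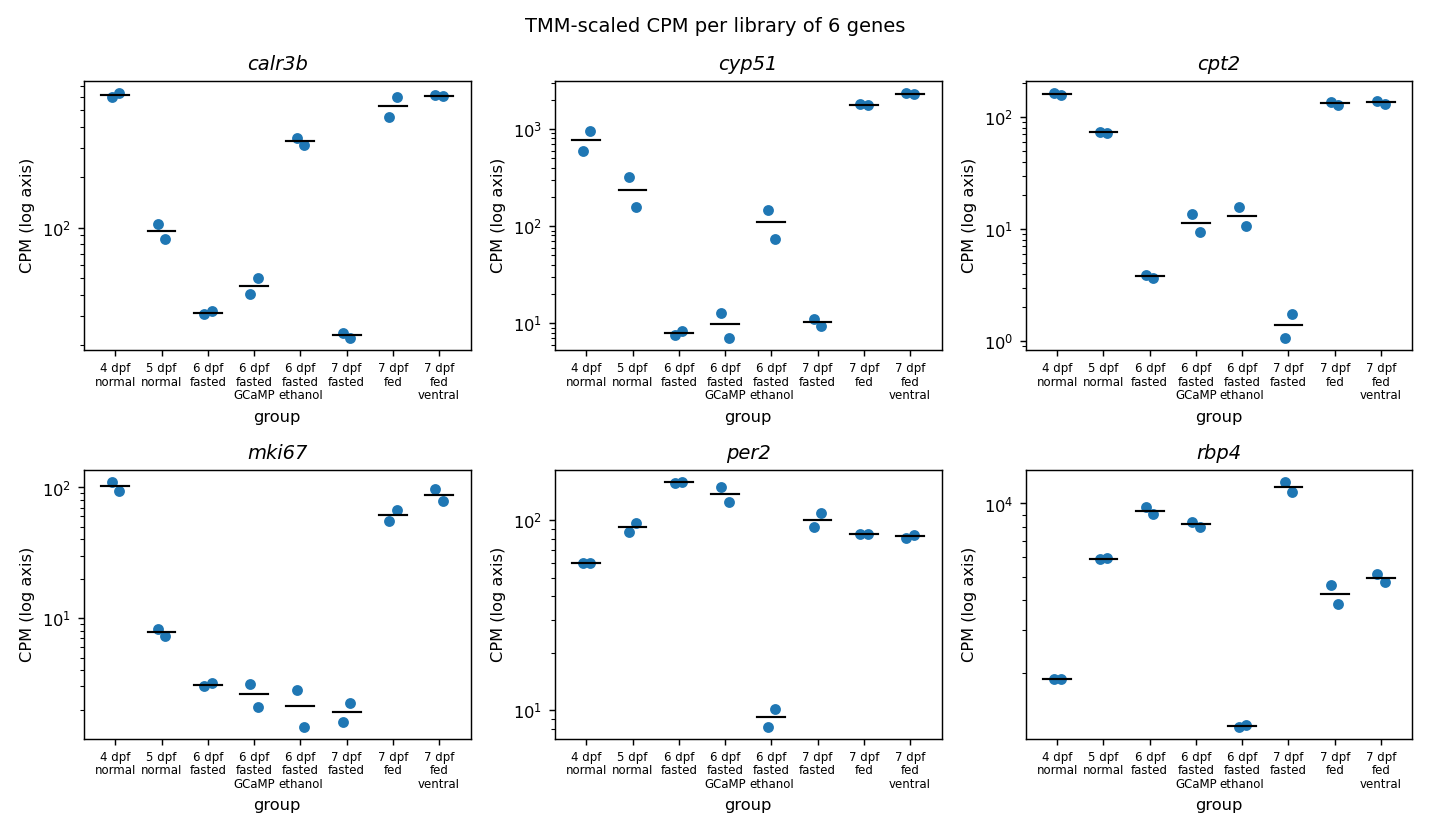
Level in CPM (log axis) of calr3b, cyp51, cpt2, mki67, per2 and rbp4 in each of the 8 groups, where each point is a library and each line the mean of 2. At 7 dpf cpt2 stood at 133 ± 5.96 CPM when fed and 1.4 ± 0.481 CPM when fasted, and at 6 dpf per2 stood at 9.22 ± 1.43 CPM with ethanol and 159 ± 0.823 CPM without.

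Fed livers labelled ventral held lower transcripts of the liver transcription factor cebpa and the growth factor igf2b, and higher transcripts of cpt1b and ppargc1b, than other fed livers. cebpa (ENSDARG00000036074) stood at 22.4 ± 3.92 CPM in ventral against 86.8 ± 2.34 CPM in other fed livers (n = 2 each). The insulin-like growth factor igf2b stood at 29.7 ± 0.825 CPM in ventral against 109.8 ± 23.6 CPM in other fed livers (n = 2 each). cpt1b (ENSDARG00000058285), which admits fatty acids to mitochondria, stood at 199 ± 2.19 CPM in ventral against 84.6 ± 7.75 CPM in other fed livers (n = 2 each). The coactivator ppargc1b stood at 51.6 ± 7.62 CPM in ventral against 21.5 ± 0.793 CPM in other fed livers (n = 2 each). The labels do not define ventral, so no question is attached to this comparison.

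The ubiquitin ligase fbxo32, a target of FOXO factors, rose (4.2 ± 0.64). The cytokine signalling inhibitor cish (-2.02 ± 0.19) and the cyclin ccnd1 (-1.59 ± 0.19) fell. Among clock genes nfil3-5 (2.98 ± 0.35) and rorcb (1.77 ± 0.29) were higher and bhlhe41 lower (-2.03 ± 0.25), while the clock list did not pass in camera. A shift in time of day would move nfil3 and bhlhe41 against each other. Collection times are not given in the sources used here, so such a shift between ventral and other fed livers is not excluded. Of hepatocyte transcription factors 0 of 22 rose and 2 fell (median -0.39, camera adjusted p = 3.25e-09, and adjusted p = 0.189 with an estimated correlation). Of exocrine pancreas markers 0 of 32 rose and 1 fell (median -2.54, camera adjusted p = 7.07e-17, and adjusted p = 0.421 with an estimated correlation). Of skin markers 0 of 28 rose and 0 fell (median 2.07, 1.47 with absent members at their bound, camera adjusted p = 0.0037, and adjusted p = 0.719 with an estimated correlation), with 5 at an unadjusted p under 0.05 and 3 called by DESeq2. Of muscle markers 0 of 35 rose and 0 fell (median 2.45, camera adjusted p = 0.00154, and adjusted p = 0.719 with an estimated correlation), with 6 at an unadjusted p under 0.05 and 5 called by DESeq2. Without ventral replicate 2 the medians of skin and muscle markers were -0.76 and -1.97, and without fed replicate 1 the muscle list no longer passed (median 1.56, camera adjusted p = 0.104). None of the 41 lists passed in camera with an estimated correlation. When adjusted over the list alone, the numbers that rose and fell differed for hepatocyte factors (0 and 3) and pancreas (0 and 26).

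Changed genes numbered 207, 89 higher and 118 lower (43% higher, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and 41.1% of all genes tested did not overlap where chance gives 33.3%. By smallest p the higher genes were raver2, the mitochondrial carrier slc25a36a, cpt1b, plekhm1, ppargc1b and the iron exporter slc40a1 (2.35-fold to 5.52-fold). The lower ones were osgn1, cish, cebpa, igf2b, tbx2b and the peroxidase gpx1b (2.56-fold to 7.91-fold lower). The highest adjusted p of these 12 was 0.000146 (edgeR, Benjamini-Hochberg). Without fed replicate 2 the number of changed genes fell to 85. The share of higher genes was 30.7% with scaling by library size alone (69 against 156), 73.5% without ventral replicate 1 and 32.7% without ventral replicate 2.

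Fasted 6 dpf livers of the GCaMP line held higher transcripts of fatty acid oxidation genes than wild type livers. cpt1b (ENSDARG00000058285) stood at 30 ± 0.611 CPM in GCaMP against 8.1 ± 0.409 CPM in wild type (n = 2 each). The acyl transferase cpt2 stood at 11.4 ± 2.98 CPM in GCaMP against 3.77 ± 0.124 CPM in wild type (n = 2 each), and the growth factor igf2a at 122 ± 13.9 CPM in GCaMP against 46.6 ± 6.56 CPM in wild type (n = 2 each). The lens crystallin cryaa (ENSDARG00000053502) stood at 8.28 ± 1.24 CPM in GCaMP and at 0 in both wild type libraries, at least 114-fold higher against a floor of 3 counts over the group. Where its reads came from was not tested. The comparison asks what the calcium reporter line changes, and EGFP, counted as a feature of its own, had 136106 and 43968 counts in the GCaMP libraries.

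Fatty acid oxidation leaned higher across its members, as 5 of 38 rose and 0 fell (median 0.54, camera adjusted p = 1.48e-27, and adjusted p = 0.0377 with an estimated correlation), with decr1 (1.5 ± 0.15) and eci1 (1.2 ± 0.15). Of bile acid genes 1 of 21 rose and 0 fell (median 0.31, camera adjusted p = 2.45e-06, and adjusted p = 0.0353 with an estimated correlation). The member that rose, the hydroxylase cyp7b1 (1.18 ± 0.22), lost its call without 6 dpf fasted replicate 2 (1.06), without GCaMP replicate 1 (0.86) and with marker scores in the model (0.88). Of calcium handling genes 0 of 42 rose and 0 fell (median -0.04, camera adjusted p = 0.695, and adjusted p = 0.844 with an estimated correlation), with 6 at an unadjusted p under 0.05 and 0 called by DESeq2. Of ribosome biogenesis genes 0 of 55 rose and 0 fell (median -0.35, camera adjusted p = 1.45e-15, and adjusted p = 0.284 with an estimated correlation), with 30 at an unadjusted p under 0.05 and 0 called by DESeq2. Of mitochondrial genome genes 0 of 13 rose and 0 fell (median -0.55, camera adjusted p = 3.38e-11, and adjusted p = 0.284 with an estimated correlation), with 12 at an unadjusted p under 0.05 and 0 called by DESeq2. They took 4.74 ± 1.03% of counts in GCaMP and 7.37 ± 0.49% in wild type. Of skin markers 0 of 28 rose and 0 fell (median -0.48, camera adjusted p = 0.0335, and adjusted p = 0.844 with an estimated correlation), with 0 at an unadjusted p under 0.05 and 0 called by DESeq2, and without 6 dpf fasted replicate 2 this list no longer passed (median -0.25, camera adjusted p = 0.319). Of exocrine pancreas markers 4 of 32 rose and 0 fell (median 1.46, camera adjusted p = 3.38e-11, and adjusted p = 0.572 with an estimated correlation). Trypsin prss1 itself, at 1911 ± 8.62 CPM in GCaMP against 657 ± 140 CPM in wild type (n = 2 each), did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.54). The tubulin tuba2 fell (-1.5 ± 0.21) and the signalling inhibitor cish rose (1.28 ± 0.17). Adjusted over the list alone, the numbers that rose and fell were the same except for fatty acid oxidation (6 and 0) and bile acid genes (2 and 0).

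The GCaMP line differed in 171 genes, 127 higher and 44 lower (74.3% higher, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and 44.3% of all genes tested did not overlap where chance gives 33.3%. The genes higher with the smallest p were cpt1b, ugt5b1, hsdl2, decr1, the corepressor tle3b and cryaa, the first 5 of them 2.42-fold to 3.7-fold. Those lower were phf20l1, tuba2, aldh3a1, crp2, sacs and nabp1a (2.01-fold to 9.56-fold lower). The highest adjusted p of the lower ones was 0.0156 (edgeR, Benjamini-Hochberg). Leaving out each library gave 55 to 237 genes (59 without 6 dpf fasted replicate 2 and 55 without GCaMP replicate 1). It ended the calls of phf20l1 (-0.95 without 6 dpf fasted replicate 1), aldh3a1 (-0.95 without 6 dpf fasted replicate 1, -0.88 without GCaMP replicate 1), sacs (-2.95 without 6 dpf fasted replicate 2, -3.15 without GCaMP replicate 1) and nabp1a (-0.95 without 6 dpf fasted replicate 2, -1.01 without GCaMP replicate 1). With marker scores in the model 73 genes differed.

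**Figure D3:**
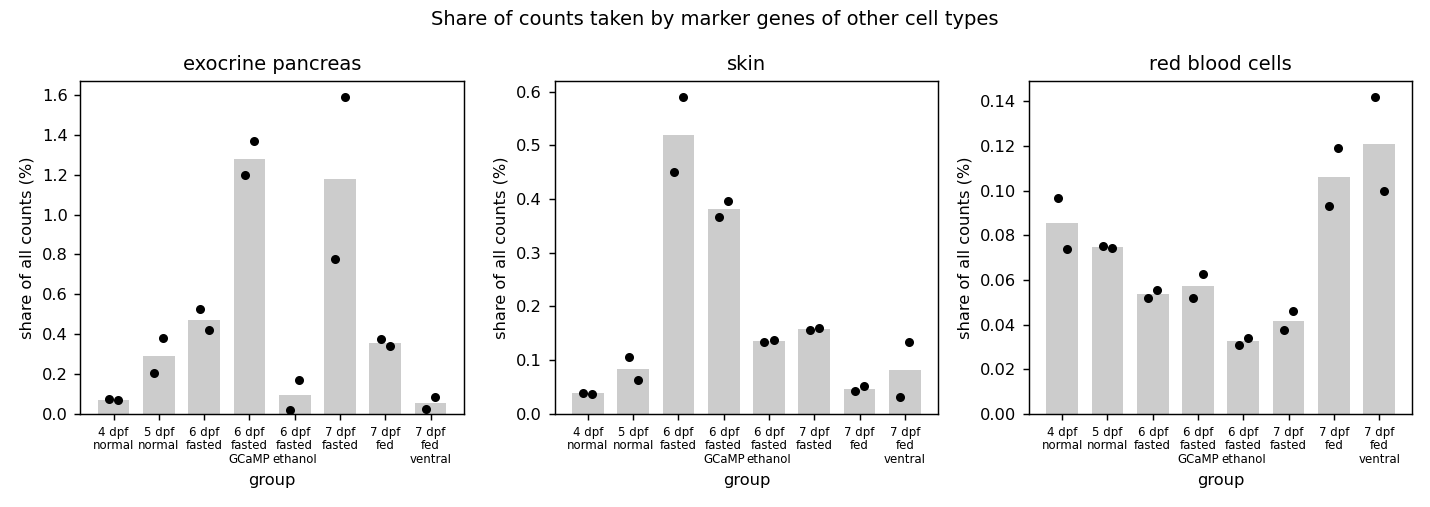
Percent of all counts taken by marker genes of exocrine pancreas, skin and red blood cells in each of the 8 groups, where bars show the mean of 2 libraries and points the libraries. Pancreas markers took 1.28 ± 0.122% in GCaMP, 1.18 ± 0.575% in 7 dpf fasted and 0.0946 ± 0.108% in ethanol livers (mean ± SD), and skin markers 0.52 ± 0.0986% at 6 dpf fasted.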

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

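The tests of both EGFP explanations and of the clock's time of day, and the marker scores, were chosen only after the result was seen. EGFP, counted as an additional feature, drew attention because it gave reads in libraries labelled wild type: 1.75 and 1.94 CPM (38 counts each) in both 6 dpf fasted wild type libraries, above the floor of 3 counts, against 6492 and 2412 CPM in the GCaMP libraries and 0 counts in the 12 others. The larger of these is 0.0437% of the GCaMP mean (the other 0.0392%), far below the 3.33% that a transgenic larva among 30 would bring, which argues against such a larva in a pool. Both levels were alike, with a ratio of 1.11, and the other libraries, those with ethanol at 6 dpf included, had 0, so carry-over of material or of index reads from the GCaMP libraries may be the source. The labels give no sequencing lanes, and no biological explanation was tested.

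Clock genes were mostly lower with ethanol, with 5 rising and 20 falling of 37. A shift in time of day would move the arm of arntl1, clock, npas2 and nfil3 against the arm of dbp, bhlhe41, nr1d1, ciart and per1a; the arms stood at -2.72 (n = 8 genes) and -0.35 (n = 7 genes), a difference of 2.37. The medians did not differ in sign as such a shift predicts, but single members did. In the first arm 7 of 8 genes were lower, and dbpa (1.05) and bhlhe41 (0.86) of the second were higher. Others of the second arm went the opposite way, with ciarta (-0.951), per1a (-0.487), nr1d1 (-0.445) and ciartb (-0.349) lower, and dbpb stood at 0.023. Collection times are not given in the sources used here, so ethanol and the time of collection cannot be told apart. With marker scores in the model 18 of the 25 changed clock genes (72%) still passed. Their median went from -2.11 to -2.1, and their median standard error from 0.229 to 0.43. The scores as fitted thus did not account for these changes. That model kept a coefficient per group, so the effect of the scores was learned only from differences between replicates. Less pancreas and skin in the ethanol libraries is therefore not excluded. An effect of ethanol on the clock stays open.

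In GCaMP livers 171 genes differed (59 without 6 dpf fasted replicate 2, 55 without GCaMP replicate 1), and an effect of the reporter protein itself stays untested. If these larvae were less advanced, changed genes would follow the difference of 4 dpf minus 7 dpf fasted; 67.3% did (74% of the higher and 47.7% of the lower genes), against 56.4% of all genes tested. Higher genes followed it and lower ones did not, so a less advanced state stays open for the former. Age and the treatment label change together along that difference, so the share cannot tell a younger state from a less fasted one. More pancreas in the GCaMP libraries stays open: with marker scores 31 of 171 (18.1%) still passed, while all 171 kept their sign and their median absolute log2 fold change went from 1.45 to 1.37 as the median standard error rose from 0.337 to 0.468; of 140 calls that ended, 109 missed the limit on adjusted p alone and 31 also that on the fold. A different haplotype around the insertion or of the line is a candidate explanation. Of the 144 genes placed on a chromosome (84.2% of 171), 41 had another changed gene among the 10 nearest on either side. In 1000 random draws the median was 25 and the 95th percentile 36 (1% as high). Without like-named neighbours it was 38 against a 95th percentile of 36 (2% as high). The 41 genes lay in 19 separate groups of neighbours, so the count does not point to a single place such as the insertion. The draws also do not allow for neighbours that are regulated together.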

How the results depend on the processing

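The marker scores and the halved counts were chosen only after the results were seen. Values below follow the order ethanol, feeding, ventral, GCaMP, 5 against 4 dpf, 6 dpf fasted against 5 dpf, 7 against 6 dpf fasted, and 7 dpf fasted against 4 dpf. Without a limit on the fold, the number of changed genes was 7901, 10224, 445, 618, 6186, 6717, 3437 and 10507. At an adjusted p under 0.05, ventral kept 124 genes and GCaMP 91, with 84.6% of the latter higher. With no count filter, ventral had 733 genes (53.8% higher) and GCaMP 461 (62.9%). DESeq2 gave 386 genes for ventral, and limma voom with sample weights 128 (53.1% higher).

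Scaling by library size alone moved the share of higher genes by over 10 points in 4 comparisons: to 80% with ethanol, 30.7% in ventral, 17.9% from 4 to 5 dpf and 32% from 4 dpf to 7 dpf fasted. It moved the median of all genes from 0 to 0.453 with ethanol, from 0.06 to -0.342 and from 0.01 to -0.327 in the latter pair, and from -0.004 to 0.189 with feeding. Under it the ethanol medians of fatty acid oxidation (-0.38 to 0.08), insulin and growth factor response (-0.14 to 0.32) and ribosome biogenesis (-0.29 to 0.17) changed sign and their calls ended. The camera adjusted p of these lists was 0.0839, 0.0427 and 0.0426 with TMM scaling, and adjusted p = 0.775, 0.584 and 0.81 with an estimated correlation, so they did not pass there either. Leaving out ethanol replicate 1 also ended the calls of the insulin (camera adjusted p = 0.17) and ribosome biogenesis lists (0.261).

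With marker scores in the model, 2521 genes changed with ethanol, 1125 with feeding (72% higher), 73 in GCaMP, 1070 from 4 to 5 dpf, 1452 from 5 to 6 dpf fasted, 547 from 6 to 7 dpf fasted and 4133 from 4 to 7 dpf fasted; ventral had 190 (60.5% higher). With the scores, camera's direction turned for cholesterol synthesis (median -0.21) and muscle markers (-0.64) in ventral, and for ribosomal proteins in GCaMP, whose median stayed positive (0.042). In the order above, 2206, 5652, 122, 140, 1902, 2134, 938 and 3314 calls ended with the scores, of which 1453, 4026, 107, 109, 1289, 1379, 636 and 1992 missed the limit on adjusted p alone.

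Leaving out each library in turn gave 3469 to 3667 genes with ethanol, 6169 to 6235 with feeding, 85 to 224 in ventral and 55 to 237 in GCaMP. The developmental comparisons gave 2200 to 2438, 2794 to 2976, 896 to 1082 and 6357 to 6511. A lone library left in a group was assumed to vary as the other groups do. At the lowest, 75.1%, 84.5%, 31.9%, 21.6%, 72.1%, 74.8%, 56% and 84.1% of the original genes were shared with the same sign. For ventral, 85 genes changed without fed replicate 2, and the share of higher genes was 73.5% without ventral replicate 1 and 32.7% without ventral replicate 2. In GCaMP, 59 changed without 6 dpf fasted replicate 2 and 55 without GCaMP replicate 1. Leaving out a library of ventral or fed turned camera's direction for some ventral lists. Their medians ranged from -0.084 to 0.312 for ribosomal proteins, -0.039 to 0.22 for oxidative phosphorylation, -1.972 to 4.385 for muscle markers and -0.76 to 2.938 for skin markers, and stayed positive for proteasome subunits (0.006 to 0.196).

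With a replicate block, 4007, 6600, 205, 166, 2612, 3169, 1175 and 6852 genes changed, and the deviations of like-numbered libraries correlated at -0.0965 to 0.111 in the comparisons and -0.24 to 0.181 over all 28 pairs of groups, which gives no sign that the numbers pair libraries. With every count halved, 4046, 6417, 205, 165, 2657, 3194, 1256 and 6681 changed. For 279 gene results named or listed, 4299 of 4468 values under these settings kept the call or its absence, 150 lost the call, 19 gained it and 0 reversed. For 167 list results, 1419 of 1651 values kept the call, 223 lost it (139 of these with the estimated correlation) and 9 turned in camera's direction. Most genes were picked for a small p or large fold in these data, and lists because they passed. The setting without a fold limit could end no call. These tallies therefore overstate how well calls held. Over all changed genes, 15.3% of the feeding calls were kept with marker scores.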

Other observations

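The overlap of ethanol with feeding was chosen only after the results were seen. With ethanol, genes of sugar metabolism leaned lower. Of gluconeogenesis genes 1 of 19 rose and 6 fell (median -0.49, camera adjusted p = 0.00587, and adjusted p = 0.472 with an estimated correlation). Of glycolysis and glycogen genes 4 of 42 rose and 11 fell (median -0.22, camera adjusted p = 0.00335, and adjusted p = 0.443 with an estimated correlation), with a median of 0.23 under scaling by library size alone. The lists of p53 targets, acute phase, hypoxia and iron genes and leukocyte markers did not pass in camera. Of p53 targets 3 of 23 rose and 5 fell (median -0.05), of acute phase genes 6 of 30 rose and 4 fell (median 0.11) and of hypoxia genes 3 of 32 rose and 4 fell (median -0.04). Of iron genes 7 of 27 rose and 3 fell (median 0.03), and of leukocyte markers 4 of 30 rose and 1 fell (median 0.06, 0.01 with absent members at their bound). When adjusted over the list alone, the numbers that rose and fell differed for gluconeogenesis (2 and 6), glycolysis (5 and 11), acute phase (8 and 4) and leukocytes (2 and 0).

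Feeding left several lists short of the camera limit. Of leukocyte markers 13 of 30 rose and 1 fell (median 1.4, camera adjusted p = 0.205, and adjusted p = 0.516 with an estimated correlation). Of acute phase genes 7 of 30 rose and 6 fell (median 0.12), and of p53 targets 3 of 23 rose and 9 fell (median -0.91). Of hypoxia genes 5 of 32 rose and 12 fell (median -0.38), of Wnt targets 1 of 16 rose and 6 fell (median -0.76) and of iron genes 9 of 27 rose and 3 fell (median 0.78). Plasma protein genes passed with the preset correlation, as 15 of 46 rose and 4 fell (median 0.33, camera adjusted p = 0.0322, and adjusted p = 0.65 with an estimated correlation). Of ribosome biogenesis genes 2 of 55 rose and 9 fell (median -0.42, camera adjusted p = 0.00156, and adjusted p = 0.516 with an estimated correlation). The numbers that rose and fell were the same adjusted over the list alone except for leukocytes (12 and 1), hypoxia (6 and 12) and iron (9 and 4).

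From 4 to 5 dpf, of p53 targets 9 of 23 rose and 1 fell (median 0.89, 0.78 with absent members at their bound, camera adjusted p = 0.000484, and adjusted p = 0.137 with an estimated correlation). Of hypoxia genes 7 of 32 rose and 0 fell (median 0.77, 0.65 with absent members at their bound, camera adjusted p = 0.0103, and adjusted p = 0.245 with an estimated correlation). Of cytosolic heat shock genes 1 of 28 rose and 13 fell (median -0.89, camera adjusted p = 0.000129, and adjusted p = 0.137 with an estimated correlation). Counts adjusted over the list alone did not differ. Over 4 dpf to 7 dpf fasted, of acute phase genes 10 of 30 rose and 2 fell (median 0.88, camera adjusted p = 0.0608, and adjusted p = 0.617 with an estimated correlation). Of proteasome subunits 0 of 41 rose and 31 fell (median -1.56, camera adjusted p = 2.1e-15, and adjusted p = 0.118 with an estimated correlation). When adjusted over the list alone, the numbers that rose and fell differed for acute phase (11 and 2). Of endocrine pancreas markers 4 of 11 rose and 0 fell (median 3.21, 2.16 with absent members at their bound, camera adjusted p = 0.00205, and adjusted p = 0.392 with an estimated correlation) from 6 to 7 dpf fasted. In ventral livers 0 of 11 rose and 1 fell (median -3.85, -2.64 with absent members at their bound, camera adjusted p = 1.4e-05, and adjusted p = 0.421 with an estimated correlation) of the same markers. Adjusted over the list alone these numbers were 8 and 0 from 6 to 7 dpf, and 0 and 7 in ventral livers. Endocrine markers took 0.00109% and 0.00623% of counts in the fed libraries and 0.000142% and 0.000276% in the ventral ones. The hormone gene gcga (-5.79) lost its call in limma voom (-5.58) and with marker scores (-5.56). It stood at -4.23 without fed replicate 2. Vitellogenins and estrogen targets passed in camera in none of the 8 comparisons; with feeding 3 of 8 rose and 1 fell (median 0.93).

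Ethanol and feeding, which share no libraries, changed many genes alike. Of the genes tested, 1009 were higher in both where independence gives 436, and 587 were lower in both where it gives 333. Another 189 were higher with ethanol and lower with feeding (354 by independence), and 300 the reverse (410). The log2 fold changes of all genes correlated at r = 0.231, a value across genes, which are not independent replicates. The unfolded protein response, the proteasome and cholesterol synthesis had higher medians in both (1.38, 1.14 and 2.42 with ethanol, 1.56, 1.81 and 5.32 with feeding), while alcohol and aldehyde enzymes moved apart (-0.95 and 1.36). Exocrine pancreas markers (medians -2.68 and -1.73) and skin markers (-2.86 and -2.38) were lower in both as well. Of 32 pancreas markers tested 9 were lower in both, and of 28 skin markers 10, against 587 of all 17799 genes. The lists hold only some genes of these tissues, so they do not bound how many of the 587 came from them.

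Marker shares differed between groups and within some of them. Pancreas markers took 0.0704 ± 0.00349% of counts at 4 dpf and 1.18 ± 0.575% at 7 dpf fasted, and 0.0568 ± 0.0426% in ventral against 0.358 ± 0.0236% in the other fed livers. Endothelial markers took 0.11 ± 0.019% in fasted and 0.0324 ± 3.08e-05% in fed livers at 7 dpf, and biliary markers 0.192 ± 0.00708% at 4 dpf and 0.517 ± 0.00602% at 7 dpf fasted.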
